A study of Mus musculus with 8 samples.

How the data were processed

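The series holds 8 samples, 4 of R1 mouse embryonic stem cells in LIF and 4 in 0.2 mM sodium butyrate for 15 passages, hybridised in pairs to 4 Agilent whole mouse genome arrays on 1 slide. Per the labels, butyrate samples carried Cy5 and LIF samples Cy3. The 8 deposited scanner files were 4 distinct files, since both samples of an array share its scan. Per the submitters' processing notes the scans were read with Agilent Feature Extraction 9.1. The deposited files give an intensity per spot and channel (mean signal, median background and a processed signal), and, per the file headers, the processed signal and the log10 ratio of Cy5 over Cy3 are background-subtracted and dye-normalized by that software. The authors' value table holds log2 values: set against the scanner files, each column correlated at 0.9996 or more with the log2 processed signal of its own channel, and each had a median of 6.487 with sorted values within 0.002 of one another, so the columns are quantile-normalized. The tool used for this is not given in the sources used here.

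From the mean signal and median background, limma 3.58.1 in R 4.3.3 corrected the background (normexp, offset 50) and normalized each array by loess with control spots at weight 0. The offset understates the fold of dim genes. Of 45018 spots per array, 43379 were not controls. Over the 4 arrays 14 spots flagged as outliers were set to missing, and spots of a probe were averaged. Of 41174 probes, 25662 were tested, those well above background on at least 3 of the 4 arrays in either channel. A gene was represented by its brightest tested probe, and 627 genes had probes that passed in opposite directions. Probes were named through the accession (22951), the symbol (6659) or a synonym (3109) in the reference table of assembly GRCm38.p6, and 8455 kept the name in the file. These gave 17190 genes, 14008 of them with a gene symbol. Where a probe was not well above background on any array of a group, a bound was set from the channel means after loess and Aquantile. For the genes named here it came out at nearly the fold of the ratio, so that fold is given and is no lower limit. For Krt8 and Krt18, saturated in butyrate, the fold of the ratio is a bound. These folds are all open to dye bias. Saturated spots were kept.

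The test was limma's lmFit and eBayes on the 4 log2 ratios of butyrate over LIF against 0, with Benjamini-Hochberg adjustment over genes. The ratio within an array takes the array out as a block, and the pairing comes from the array shared by both samples of a replicate number. As a check, the deviations of same-numbered samples from their group means correlated, across genes, at 0.2976, 0.1584, 0.3061 and 0.2255. Samples of other numbers gave −0.2134 to 0.1009. Since samples of the same number share an array, this does not show whether their cultures were paired. A list of genes was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Values are log2 ratios ± SD over 4 arrays. All arrays lay on 1 slide with 1 scan day, so no batch could be tested.

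Before the data were examined, 31 lists of 578 entries were fixed, of which 567 were on the array and 538 tested. Genes named are the 10 largest increases and decreases among genes with a symbol and the same sign on the 4 arrays, up to 4 members of each list with the largest change that passed, and Pou5f1, Sox2, Nanog, Klf4, Zfp42, Esrrb, Fgf5, Dnmt3b, Stat3, Socs3 and Cdkn1a. Some genes that the rule picks are not reported here, and no others take their place. A named gene whose other probes disagree is named with that fact. Other members of the lists were named after their values were seen. Alternatives were no background correction, a normexp offset of 16, the scanner software's log ratio, centring on the median without loess, Aquantile, other filters on dim, flagged or saturated probes, other ways to combine probes, another variance model, fits with no replicate block or with a random one, each replicate left out, and the authors' value table.

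The steps were tested on simulated data with 17191 genes for butyrate against LIF, 200 of them changed. Of 25 genes raised and 25 lowered at each size, 25 and 24 were recovered at 2-fold, 23 and 20 at 1.5-fold, and 11 and 3 at 1.2-fold, and 11 of 16991 unchanged genes were called. The simulation changed few genes, as many up as down, and held no dye bias shared by the arrays. These counts are therefore no error rate for the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.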

Results

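RNA of R1 mouse embryonic stem cells, a line of pluripotent cells from the early embryo, was measured on 4 Agilent whole-genome mouse arrays with 2 colours. The cells grew on gelatin in a medium with serum replacement. In 1 group of 4 samples they were kept with leukaemia inhibitory factor (LIF), the cytokine that holds mouse embryonic stem cells undifferentiated, without feeder cells. In the other group of 4 samples they were kept without LIF in 0.2 mM sodium butyrate, a short-chain fatty acid that inhibits histone deacetylases, for 15 passages. Each array carried 1 butyrate sample labelled with Cy5 and the LIF sample of the same replicate number labelled with Cy3. Every array had this orientation, so dye and treatment cannot be told apart, and a bias of a dye for a transcript stays in each ratio. The number of arrays limits the precision. The median signal was 62.8 to 66.0 in Cy3 and 110 to 111.4 in Cy5, and 57.9% to 61.2% of non-control spots in the LIF channel and 62.7% to 63.9% in the butyrate channel were well above background. The labels call the replicates independent but name no separate line or derivation, so the p-values measure the spread between these samples, which may be partly technical.

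The comparison asked how the RNA profile of cells kept in butyrate differed from that of cells kept in LIF. The lists of trophoblast, fibroblast and 2-cell embryo genes rose in butyrate, and those of naive pluripotency and of the response to LIF fell, by camera with its preset correlation. None of the 5 passed with an estimated correlation (adjusted p = 0.396 to 0.505). With loess normalization the largest increase was that of Pmp22, a myelin and membrane protein, which was 26.2-fold higher (log2 ratio 4.71 ± 0.26, SD, n = 4 arrays). Col1a1, a chain of type I collagen, followed at 17.7-fold (4.15 ± 0.16). Among the decreases, Inhbb, the activin beta B subunit, was 8.97-fold lower (−3.17 ± 0.28). Of 17190 genes tested with limma, 12889 (74.98%) passed an adjusted p of 0.05, 7173 higher and 5716 lower in butyrate. Most of these changes were small: the median absolute log2 ratio of the genes that passed was 0.36, and 9406 of them (73.0%) changed by less than 1.5-fold. At least 2-fold changes were found for 1192 genes, 854 higher and 338 lower, and at least 4-fold changes for 115 higher and 26 lower. The split depended on the scaling: with each array centred on its median and no loess, the median of all genes moved from 0.03 to 0.41 and 92.4% of the genes that passed were higher, against 55.7%. Ratios are therefore relative to the centre set by the loess. The count of 2-fold changes was then 2851, and it was 2987 with the scanner software's own log ratio and 2973 with the authors' value table. The median ratios of genes of chromosomes 8, 11 and 19 lay 0.30, 0.22 and 0.19 above that of the other autosomes. With these genes left out of the counts after seeing the data, and no new fit, 10884 genes passed, 5591 higher and 5293 lower.

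The other genes among the 10 largest increases were Itga11, a collagen-binding integrin (log2 ratio 3.84 ± 0.55), Sct, the hormone secretin (3.55 ± 0.11), Gjb2, a gap junction protein (3.51 ± 0.53), and Mogat2, an acyltransferase of fat absorption (3.42 ± 0.18). Ctla2a, a protease inhibitor (3.34 ± 0.52), Postn, the matrix protein periostin (3.22 ± 0.47), Esx1, a placental homeobox factor (3.14 ± 0.22), and Msx2, a homeobox target of BMP signalling (3.12 ± 0.39), completed them. On array 2 the ratios of Itga11, Gjb2, Postn and Msx2 stood apart from those of the other arrays, at 3.02, 2.72, 2.51 and 2.55. Beside Inhbb, large decreases were those of Lrrc34 (−3.15 ± 0.13), Calml4 (−3.10 ± 0.13), Aass, an enzyme of lysine breakdown (−3.09 ± 0.14), and Gbx2, a homeobox target of LIF signalling (−2.81 ± 0.20). Igsf21 (−2.52 ± 0.15), Nr0b1, a nuclear receptor of the stem cell state (−2.42 ± 0.04), Dpys, an enzyme of pyrimidine breakdown (−2.41 ± 0.05), and Bcl3, a STAT3 target (−2.40 ± 0.08), followed. All 19 genes had the same sign on the 4 arrays. The order depended on the processing: with the scanner software's log ratio Itga11 (5.75), Ctla2a (5.66) and Gjb2 (5.64) lay above Pmp22 (5.11), and with the authors' value table too (5.73, 5.62 and 5.61 against 5.08). Other probes gave smaller ratios for Col1a1 (2.09), Gjb2 (0.38) and Inhbb (−0.57).

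**Figure D1:**
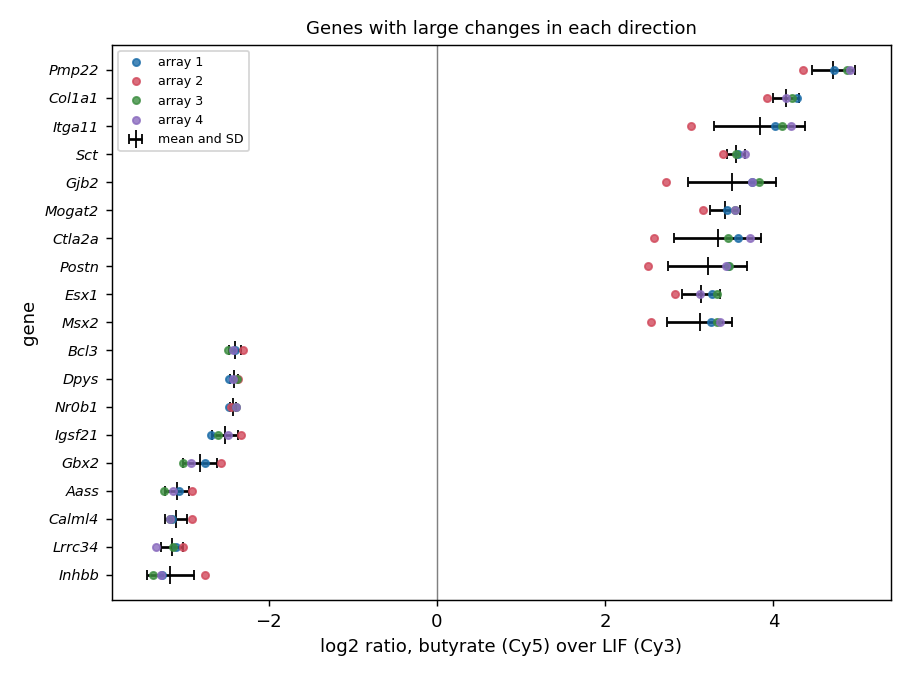
The log2 ratio of butyrate over LIF (x axis) is plotted for the 10 genes with the largest increase and 9 with a large decrease (y axis), with a point per array and the mean and SD of 4 arrays. The means run from −3.17 for Inhbb to 4.71 for Pmp22.

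Markers of pluripotency fell unevenly. Of 21 naive pluripotency genes tested, 17 were lower, 2 were higher (Tbx3 and Dppa3) and 2 did not pass. Gbx2 and Nr0b1 led, followed by Tfcp2l1 (4.37-fold lower, −2.13 ± 0.19), a transcription factor of the naive network, and Tcl1 (3.92-fold, −1.97 ± 0.10), a cofactor of the kinase AKT. Esrrb fell 2.99-fold (−1.58 ± 0.05) and Klf4 2.62-fold (−1.39 ± 0.15). Zfp42, a widely used marker also known as Rex1, was lower by only 1.14-fold (−0.19 ± 0.10), and lay at 0.27 when arrays were centred on the median. The list as a set fell (camera adjusted p = 2.29e-05; adjusted p = 0.396 with an estimated correlation). Of 16 core pluripotency genes, 12 were lower and 3 higher. Pou5f1, which encodes OCT4, fell 2.98-fold (−1.57 ± 0.22), Sox2 2.36-fold (−1.24 ± 0.09), Utf1 2.14-fold (−1.1 ± 0.05) and Foxd3 2.13-fold (−1.09 ± 0.06). Nanog was slightly higher, by 1.18-fold (0.23 ± 0.05). This list also passed (adjusted p = 0.00298; adjusted p = 0.396 with an estimated correlation), and when arrays were centred on the median, which moved the median of all genes to 0.41, its mean of −0.54 became 0.013 and it still passed (adjusted p = 0.00146; 0.000177 to 0.0189 over the alternatives). Dppa5a, a member, was saturated in both channels and has no usable fold.

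Genes that respond to LIF and its transcription factor STAT3 were lower in the cells grown without LIF. Of 18 tested, 14 were lower, 2 were higher and 2 did not pass (adjusted p = 0.000162; adjusted p = 0.396 with an estimated correlation). Bcl3 was 5.27-fold lower, Mras, a small GTPase, 3.56-fold (−1.83 ± 0.04) and Socs3, the feedback inhibitor of the pathway, 3.02-fold (−1.59 ± 0.05). Stat3 itself was 1.88-fold lower (−0.91 ± 0.13), and with centring on the median it no longer passed (−0.32). Pramel7 and Junb were higher. 4 of the listed genes, Klf4, Klf5, Tfcp2l1 and Gbx2, are also in the naive list.

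**Figure D2:**
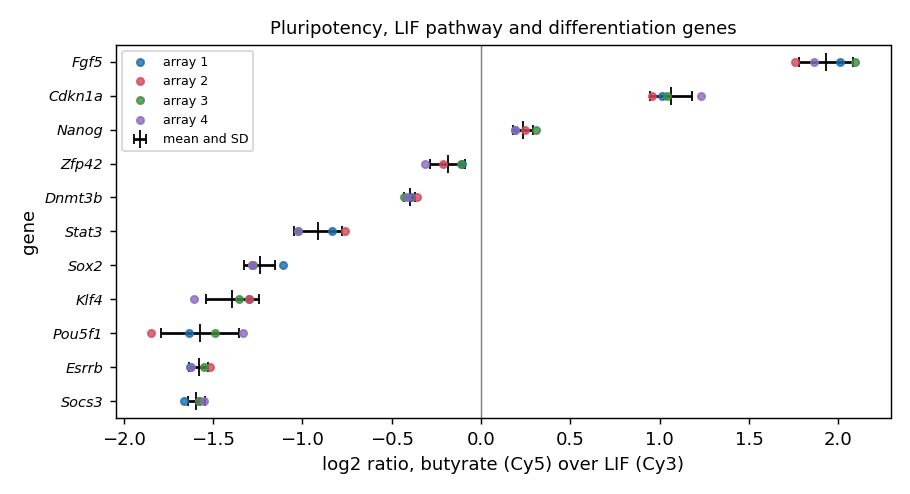
The log2 ratio of butyrate over LIF (x axis) is plotted for the 11 genes of pluripotency, the LIF pathway, differentiation and growth arrest chosen before the data were examined (y axis), with a point per array and the mean and SD of 4 arrays. Fgf5 lies highest at 1.93 and Socs3 lowest at −1.59, and Zfp42 and Dnmt3b, below 0 here, lay above 0 when arrays were centred on the median.

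Genes of the trophoblast, the lineage that forms the placenta, rose. Of 16 tested, 15 were higher and 1, Fgfr2, was lower (adjusted p = 0.000162; adjusted p = 0.396 with an estimated correlation). Krt19, a keratin of simple epithelia, was 7.61-fold higher (2.93 ± 0.09), Cdx2, a transcription factor that specifies trophectoderm, 6.81-fold (2.77 ± 0.45), and Gata2 6.30-fold (2.66 ± 0.31). The keratins Krt8 and Krt18 were saturated in the butyrate channel on the 4 arrays, so they were at least 3.85-fold and at least 3.55-fold higher. In all, 10 of the 15 genes were at least 2-fold higher, while Tead4 (0.10 ± 0.03), Tfap2c (0.15 ± 0.11) and Ascl2 (0.16 ± 0.09) rose by less than 1.2-fold. Elf5 and Dlx3 were not well above background in LIF, and Tpbpa was not well above background in either group. Of 12 genes of the 2-cell embryo, 11 were higher and 1, Eif1a, was lower in its brightest probe while another probe passed in the opposite direction (adjusted p = 0.000181; adjusted p = 0.505 with an estimated correlation). Calcoco2 was 6.50-fold (2.70 ± 0.06), Zscan4c 5.45-fold (2.45 ± 0.06), Usp17la 5.37-fold (2.43 ± 0.11) and Tcstv1 4.40-fold higher (2.14 ± 0.05). Zscan4, Usp17l and Tcstv genes have near-identical copies, and whether the probes tell these apart was not tested.

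Markers of fibroblasts, the cell type used as feeders, were higher for 17 of 19 genes (adjusted p = 0.000162; adjusted p = 0.396 with an estimated correlation). After Col1a1 and Postn, Col5a1 was 3.64-fold (1.86 ± 0.06) and Col1a2 3.29-fold higher (1.72 ± 0.13). Thy1 (−0.18 ± 0.06) and Twist1 (−0.24 ± 0.07) were lower, Dcn, not well above background in LIF, was 1.07-fold higher (0.09 ± 0.04), and Lum was not well above background. Of 8 haematopoietic markers, 6 were higher, led by Csf1r (0.99 ± 0.31), Cd34 (0.94 ± 0.09) and Runx1 (0.41 ± 0.10), but the list did not pass (adjusted p = 0.179) except with probes counted singly (adjusted p = 0.0471; 0.0471 to 0.465 over the alternatives). Lyz2, well above background in the butyrate channel only, was 1.165-fold higher (0.22 ± 0.11), and did not pass with centring on the median (0.12).

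Genes of the primitive streak and mesoderm were higher for 11 of 15, with 1 lower (12 in all, and 13 adjusted over the list alone; adjusted p = 0.029; adjusted p = 0.505 with an estimated correlation). Hand1, also in the trophoblast list, was 5.80-fold (2.53 ± 0.20), Wnt3 4.20-fold (2.07 ± 0.24), T, the mesoderm factor brachyury, 3.68-fold (1.88 ± 0.41) and Fgf8 3.32-fold higher (1.73 ± 0.28). The list no longer passed with the strict filter on dim probes (adjusted p = 0.0639; 0.00303 to 0.0639 over the alternatives). Genes of extraembryonic and definitive endoderm were higher for 14 of 21 and lower for 4 (adjusted p = 0.033; adjusted p = 0.396 with an estimated correlation; adjusted p = 0.213 with centring on the median, and 0.00689 to 0.213 over the alternatives). The basement membrane collagens Col4a1 (6.51-fold, 2.70 ± 0.11) and Col4a2 (4.96-fold, 2.31 ± 0.07) and the matrix protein Sparc (3.84-fold, 1.94 ± 0.03) rose, and Apoe fell 2.62-fold (−1.39 ± 0.08). Primed epiblast genes were higher for 11 of 20 and lower for 5 and did not pass as a set (adjusted p = 0.242). Among them Fgf5 was 3.81-fold (1.93 ± 0.15), Wnt8a 2.60-fold (1.38 ± 0.31) and Fst 2.15-fold higher (1.1 ± 0.15), and Lefty2 2.13-fold lower (−1.09 ± 0.14). Dnmt3b was 1.32-fold lower (−0.40 ± 0.03), but lay at 0.15 with centring on the median. Neural genes went both ways, 6 higher and 6 lower of 17 (adjusted p = 0.73), with Nefm (1.59 ± 0.25), Sox11 (1.21 ± 0.10) and Nes (1.08 ± 0.13) higher and Stmn3 lower (−1.38 ± 0.19).

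**Figure D3:**
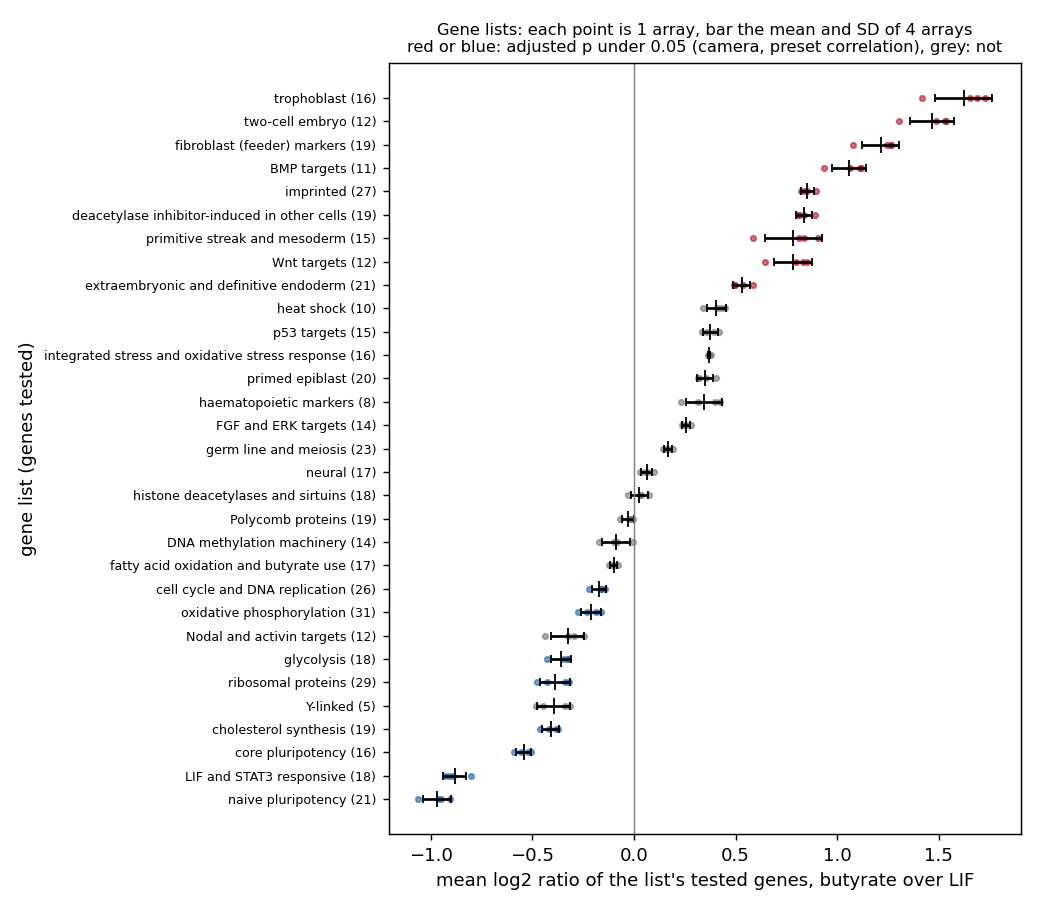
The mean log2 ratio of butyrate over LIF (x axis) over the tested genes of each list (y axis, with the number of genes) is plotted with a point per array and the mean and SD of 4 arrays; red and blue lists passed camera's test with its preset correlation of 0.01 and grey lists did not. Means run from −0.97 for naive pluripotency to 1.62 for trophoblast, and with centring on the median the means of the core pluripotency, glycolysis, oxidative phosphorylation, cholesterol, cell cycle and ribosomal lists lay above 0, with the median of all genes at 0.41.

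Genes known to rise with deacetylase inhibitors in other cells were higher for 15 of 19 (adjusted p = 0.00329, and adjusted p = 0.396 with an estimated correlation). The 4 others, Cdkn1b, Cdkn2d, Txnip and Gadd45a, were lower, Gadd45a most (−1.07 ± 0.10). Krt8 and Krt18, among those higher, are also in the trophoblast list. The actin-severing protein Gsn was 5.53-fold higher (2.47 ± 0.04) and the cell cycle inhibitor Cdkn2b 3.70-fold (1.89 ± 0.09). Cdkn1a, which encodes the inhibitor p21, was 2.09-fold higher (1.06 ± 0.12). Imprinted genes, expressed from 1 parental copy, were higher for 22 of 27 and lower for 4 (adjusted p = 0.000181; adjusted p = 0.396 with an estimated correlation). Plagl1 was 7.76-fold (2.96 ± 0.25), H19 5.29-fold (2.40 ± 0.04), Sgce 4.14-fold (2.05 ± 0.05) and Mest 3.99-fold higher (2.00 ± 0.03). The histone deacetylases and sirtuins, which include the targets of butyrate, showed no common direction (7 higher and 8 lower of 18, adjusted p = 0.73), with Hdac7 (0.90 ± 0.06), Sirt7 (0.88 ± 0.04) and Sirt4 (0.58 ± 0.06) higher and Sirt5 lower (−0.59 ± 0.06). The DNA methylation machinery (4 higher and 6 lower of 14, adjusted p = 0.544) included Tet1 (−1.39 ± 0.34) and Dnmt3l (−0.80 ± 0.04), both lower, and Mbd1 (0.97 ± 0.04) and Mbd2 (0.74 ± 0.08), both higher. Polycomb proteins (7 higher and 8 lower of 19, adjusted p = 0.454) included Suz12 (0.65 ± 0.20), higher, and Phf19 (−1.0 ± 0.07) and Eed (−0.76 ± 0.03), lower. Germ line genes went both ways (10 higher and 11 lower of 23, adjusted p = 0.931), with the X-linked homeobox genes Rhox6 (2.70 ± 0.07) and Rhox9 (2.43 ± 0.07) higher and the meiotic genes Sycp3 (−1.97 ± 0.21) and Hormad1 (−1.48 ± 0.24) lower. With centring on the median Sirt5, Dnmt3l and Eed no longer passed. For the neural, germ line and deacetylase lists the mean lay above 0 while the median and the test lay below it.

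Targets of BMP signalling were higher for 9 of 11 (adjusted p = 0.0123; adjusted p = 0.396 with an estimated correlation). After Msx2, the inhibitors of differentiation Id3 (3.50-fold, 1.81 ± 0.15), Id1 (3.48-fold, 1.80 ± 0.13) and Id2 (3.39-fold, 1.76 ± 0.18) rose most. Wnt targets were higher for 9 of 12 (adjusted p = 0.0131; adjusted p = 0.396 with an estimated correlation), with the Wnt antagonist Dkk1 at 7.50-fold (2.91 ± 0.44), the feedback gene Axin2 at 2.62-fold (1.39 ± 0.12) and Sp5 at 2.25-fold (1.17 ± 0.16). Of 12 Nodal and activin targets, 4 were higher and 4 lower (adjusted p = 0.498), with Inhbb 8.97-fold and Lefty1 4.70-fold lower (−2.23 ± 0.11). FGF and ERK targets were split 7 to 7 (adjusted p = 0.906), with Phlda1 (1.85 ± 0.12), Dusp4 (1.64 ± 0.04) and Ier3 (1.31 ± 0.11) higher and Spry4 lower (−1.1 ± 0.31). Targets of p53 were higher for 10 of 15 (adjusted p = 0.242), with Fas (1.63 ± 0.29), Perp (1.33 ± 0.14) and Mdm2 (0.92 ± 0.09) beside Cdkn1a. Stress response genes were higher for 9 of 16 (adjusted p = 0.409), with Hmox1, a haem-degrading enzyme, 6.91-fold higher (2.79 ± 0.21), Atf3 (2.00 ± 0.08) and Sqstm1 (1.69 ± 0.06) higher, and Trib3 lower (−1.73 ± 0.10). Heat shock genes were higher for 5 of 10 (adjusted p = 0.509), led by Hspa1a (2.42 ± 0.09), Dnajb1 (1.08 ± 0.01), Bag3 (0.80 ± 0.04) and Hspb1 (0.76 ± 0.08). Whether the Hspa1a probe also reads its near-identical copy was not tested.

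Genes of energy metabolism and growth were mostly lower with loess normalization, by small amounts. With centring on the median the means of 4 of these lists lay above 0, but below the median of all genes, which was then 0.41. Glycolysis genes were lower for 15 of 18 (adjusted p = 0.00178; adjusted p = 0.396 with an estimated correlation), with a mean of −0.36 that became 0.15 with that centring, where the list still passed (adjusted p = 0.0054; 1.38e-05 to 0.0189 over the alternatives). Aldoa, counted as lower, was saturated in both channels and has no usable fold. Pdk1, a kinase that inhibits pyruvate dehydrogenase, fell 3.47-fold (−1.79 ± 0.06) and Aldoc 3.02-fold (−1.59 ± 0.12). The 3 members that rose were the glucose transporters Slc2a1 (2.75-fold, 1.46 ± 0.03) and Slc2a3 (2.64-fold, 1.40 ± 0.12) and the lactate transporter Slc16a3. Oxidative phosphorylation genes were lower for 20 of 31 (adjusted p = 0.00329; adjusted p = 0.505 with an estimated correlation), with a mean of −0.21 that became 0.31 with centring on the median (adjusted p = 0.48; 0.000741 to 0.48 over the alternatives). Sdhc (−0.69 ± 0.03), Cox7c (−0.67 ± 0.22), Cox6c (−0.64 ± 0.10) and Sdhb (−0.60 ± 0.13) led, and with that centring none of these 4 passed. Cholesterol synthesis genes were lower for 14 of 19 (18 genes passed adjusted over the list alone, against 17; adjusted p = 0.00132; adjusted p = 0.396 with an estimated correlation), with a mean of −0.41 that became 0.15 with centring on the median, where the list still passed (adjusted p = 0.0133; 2.08e-05 to 0.0133 over the alternatives). Lss (−1.05 ± 0.12), Hmgcs1 (−0.88 ± 0.11), Mvk (−0.88 ± 0.03) and Insig1 (−0.87 ± 0.19) were among them, and of these 4 only Lss passed with that centring. Cell cycle genes were lower for 17 of 26 (adjusted p = 0.00642; adjusted p = 0.396 with an estimated correlation), with a mean of −0.17 that became 0.35 with centring on the median (adjusted p = 0.535; 0.0016 to 0.535 over the alternatives). Bub1b (−0.78 ± 0.09), Aurka (−0.57 ± 0.05) and Bub1 (−0.52 ± 0.16; 0.066 with centring on the median) were lower, none of them with that centring, and Ccnd2 higher (0.81 ± 0.07). Genes of fatty acid oxidation and butyrate use were split 7 to 7 of 17 (adjusted p = 0.487), with Acadvl higher (1.29 ± 0.03) and Bdh1 (−0.94 ± 0.05), Echs1 (−0.87 ± 0.05) and Acadm (−0.84 ± 0.04) lower, the last 3 not with centring on the median.

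For ribosomal protein genes the direction depended on saturated probes. Of 29 tested, 23 passed as lower (adjusted p = 2.12e-05; adjusted p = 0.505 with an estimated correlation), but 21 of the 29 were saturated in the butyrate channel on the 4 arrays, and these had a median log2 ratio of −0.59 against −0.15 for the other 8. Rplp1, Rps14, Rps18 and Rplp0 were saturated in both channels, at nearly the same ratio of −0.61, and have no usable fold; other probes of Rps18 passed in both directions. With saturated probes left out the mean of the list was 0.17 (adjusted p = 0.856; 2.28e-07 to 0.856 over the alternatives), and with centring on the median 0.050 (adjusted p = 0.000235). Among all genes, 155 were saturated in the butyrate channel on the 4 arrays, of which 118 passed as lower. Y-linked genes did not pass as a set (adjusted p = 0.242) except with centring on the median (adjusted p = 0.0175; 0.0175 to 0.343 over the alternatives). Ddx3y was 2.48-fold lower (−1.31 ± 0.16), Uty 1.46-fold (−0.54 ± 0.17) and Eif2s3y 1.24-fold (−0.31 ± 0.15, and 0.28 with centring on the median). Kdm5d, not well above background in LIF, was 1.1-fold higher (0.14 ± 0.07). It did not pass without replicate 3 (0.12) or with centring on the median.

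The size of a change often differed between probes of a gene. Of 52 named genes with more than 1 tested probe, 25 had another probe more than 1.5-fold away. Beside Col1a1, Gjb2 and Inhbb, the other probe gave a smaller ratio for Plagl1 (0.65), Dkk1 (0.85), Hspa1a (0.65), Col5a1 (0.11), Tfcp2l1 (−0.44), Aldoc (−0.07), Mras (−0.32), Esrrb (−0.13) and Fgf8 (0.49). It was also smaller for Slc2a3 (0.20), Hormad1 (−0.49), Sox11 (0.26), Dnajb1 (0.15), Spry4 (−0.22), Mbd1 (0.13), Csf1r (0.26), Bdh1 (−0.25) and Dusp4 (1.01). H19 had a larger one (3.76), and Hmgcs1 (0.018), Rps18 (0.40) and Rplp0 (0.033) had one with the other sign.

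By camera with the preset correlation 17 of the 31 lists passed, 9 higher and 8 lower, and with an estimated correlation 0 passed. By fry, which does not compare a list with other genes, 30 passed. For 29 of the 31 lists the number of genes that passed adjusted over the list alone was the number that passed over all genes tested.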

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

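Of the tests in this part, those of the split of the samples and of a second probe over all genes that passed were set before their results were seen; those on changes under 1.2-fold and on other cell types were chosen afterwards.

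In 11 of 136 named genes 1 array stood far from the other 3, where chance sets apart about 1 in 20 groups. In 8 of the 11 it was array 2, with log2 ratios of 3.02 for Itga11, 2.72 for Gjb2, 2.51 for Postn, 2.55 for Msx2, −2.91 for Calml4, 1.27 for T, 1.22 for Nefm and 2.25 for Dkk1. On array 1 Sox2 lay at −1.11 and Lss at −1.23, and on array 4 H19 lay at 2.34. The mean of the fibroblast list was 1.08 on array 2, against 1.25 to 1.27 on the others. The LIF channel of array 3 had 65 saturated spots, against 49 to 51. Without replicate 2 the number of genes that passed was 12803.

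The number of genes that passed is high for 4 arrays. Without the array block 12507 genes passed, and of the 35 splits of the 8 samples only 1, the real one, gave as many. The highest of the others gave 0, and so did those of the others that part all 4 pairs. This cannot decide on chance, because a split that mixes the groups puts the group difference into the spread within each part. With the pairs kept there were only 8 sign assignments of the ratios, of which 1, the real one, gave as many calls. Those are too few to decide, and the replicates may be partly technical. A bias of the dyes for single probes would leave the sign of a second probe of the gene to chance. Of 4839 genes that passed and had a second tested probe, 81.53% had the same sign in it. The share was 76.61% of all 6085 genes with a second probe, which include those 4839. The share was 97.2% of those changed at least 2-fold and 76.6% of those changed less than 1.5-fold. This argues against such a bias as the whole cause only as far as the probes of a gene differ in sequence. Overlapping probes would share a bias, and their overlap could not be checked. For changes under 1.2-fold the share was 68.33%, which leaves such a bias open there, and a dye bias shared by all probes of a transcript cannot be told apart from the treatment in any gene, because no dyes were swapped. A response to butyrate or to the loss of LIF stays open as the biological explanation, and the design does not separate them, nor from time in culture, since the labels do not make clear how many passages the LIF cells had.

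By camera with its preset correlation the trophoblast and fibroblast lists rose while the core and naive pluripotency lists fell, each with adjusted p = 0.396 with an estimated correlation. A lower share of stem cells alone was predicted to raise the markers of other types alike. The mean of the trophoblast list exceeded that of the neural list by 1.56 (permutation p = 0.00035, 2-sided, 16 and 17 genes). This cannot decide the question, because the lists compared were chosen after their values were seen. The permutation also took genes as independent, while the estimated correlation within the trophoblast list was 0.31. A lower share of stem cells, a gain of trophoblast-like cells and a gain of these genes within stem cells all stay open. Feeder fibroblasts cannot be told apart from expression by the cells themselves. In the fibroblast list 17 of 19 members were higher (Thy1 and Twist1 were lower), 15 of the 19 were well above background in LIF cells too and 1 is in another list. The probes brightest in butyrate had mean log2 intensities of 15.42 in butyrate and 13.72 in LIF (Tagln), 13.95 and 12.85 (Acta2), 13.61 and 12.30 (Vim) and 12.72 and 8.58 (Col1a1). Col3a1 lay at 7.65, Lox at 7.06, Col6a1 at 6.88 and Dcn at 6.45 in butyrate, and Lum was not well above background. Intensities cannot be compared between probes, so they do not rank these genes by RNA level. The labels name gelatin as the substrate, and no fibroblast sample is here to set the share.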

How the results depend on the processing

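Alternatives were chosen before the data were examined, except the count without chromosomes 8, 11 and 19, chosen after seeing the data. That count only drops genes from the main fit, with no new normalization or test. The number of genes that passed was 12889, and 10547 to 13715 over the alternatives that count genes; it was 18538 with probes counted singly, 10884 without those chromosomes, and 11569 to 12803 with a replicate left out. With no replicate block 12507 genes passed and with the replicate block as a random effect 12951; neither changed the call of a named gene, and the lists could not be tested in the random fit. At least 2-fold changes numbered 2987 with the scanner software's log ratio (1904 higher, 1083 lower), 2973 with the authors' value table (1836 and 1137) and 2851 with centring on the median (2774 and 77), against 1192. With centring on the median 798 genes were lower and 92.4% of calls higher; 47.3% were higher with the scanner's ratio and 46.0% with the authors' table. The cause was not tested. By list, 0 passed with an estimated correlation and 30 by fry.

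Of 2578 comparisons of named genes with an alternative, 2548 kept their direction and side of the threshold, 29 no longer passed (26 of them with centring on the median, and 5 with the other sign) and 1, Rps18 with saturated probes left out, passed with the other sign. Of 557 for lists, without the other set tests, 545 did so, 6 no longer passed (3 with the other sign of the mean), 2 passed anew and 4 passed with the other sign of the mean. Aquantile, the other variance model and the fits of the replicate block left the ratios of the largest changes as they were. Most named genes were also picked because they passed with a large change. The share of gene comparisons that held was therefore partly set in advance. With centring on the median Bub1 (0.0656), Eif2s3y (0.28), Zfp42 (0.27) and Dnmt3b (0.15) changed sign, as did the means of the lists of core pluripotency (0.0132), glycolysis (0.15), oxidative phosphorylation (0.31), cholesterol synthesis (0.15), cell cycle (0.35) and ribosomal proteins (0.0495); that centring leaves the trend with intensity in the ratios and moved the median of all genes to 0.41. Of these lists oxidative phosphorylation (adjusted p = 0.48) and cell cycle (adjusted p = 0.535) no longer passed. With saturated probes left out Rps18 (0.40), Rplp0 (0.0334) and the ribosomal list (0.17) changed sign, since other probes then stand for these genes. Without replicate 3 Kdm5d no longer passed (0.12). With the authors' table Rps18 and the ribosomal list did not pass. Signal over background limits dim genes: 599 genes were not well above background in LIF on any array and 70 in butyrate.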

Other observations

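All tests in this part were chosen after the result was seen. Genes of chromosomes 8, 11 and 19, placed by the table of assembly GRCm38.p6, were higher in butyrate than genes of the other autosomes. The median log2 ratio lay above that of the others by 0.30 on chromosome 8 (764 genes, 516 passing as higher and 107 as lower), by 0.22 on chromosome 11 (1249 genes, 761 and 219) and by 0.19 on chromosome 19 (524 genes, 305 and 97). On single arrays the shifts were 0.25 to 0.32, 0.18 to 0.24 and 0.14 to 0.21. The other autosomes lay between −0.058 and 0.057, and chromosome X at 0.13. Camera with the preset correlation gave adjusted p = 1.84e-07, 4.21e-05 and 0.00135 over 20 chromosomes, and adjusted p = 0.254 for each with an estimated correlation. Chromosome 7 passed in the other direction (shift −0.058, 378 genes higher and 533 lower, adjusted p = 0.0314; adjusted p = 0.254 with an estimated correlation). Over the alternatives the lowest shifts were 0.17, 0.12 and 0.08, with no filter on dim probes, and the highest 0.41, 0.33 and 0.29. On the other autosomes 49.2% of the genes that passed were higher, against 55.7% of all.

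A few strongly induced genes would leave the lower part of the distribution in place, but the 25th percentile of each of the 3 chromosomes lay at least 0.22 above that of the other autosomes. A local cluster would leave parts of a chromosome in place, but 10 of 10 windows of gene order on each lay above the median of the others. The count alone does not set the 3 apart, since it was also 10 on chromosome X and 9 on each of chromosomes 1, 6 and 12. The lowest window lay at 0.14, 0.13 and 0.08 on chromosomes 8, 11 and 19, against 0.0089 on X. Of 10000 random sets of genes matched on mean intensity, 0 reached the median of any of the 3. This cannot decide on probe intensity as a cause. The loess had already taken the trend with intensity out of the ratios, so matched sets had to lie near 0. A candidate explanation is an extra copy of these chromosomes in part or all of the butyrate cells, gains of chromosomes 8 and 11 being known to recur in cultured mouse embryonic stem cells. The highest shift, 0.2998, is below the 0.585 that 3 copies against 2 would give in every cell without compression. But the processing compresses ratios: simulated increases of 0.585 were estimated at a median of 0.4775. With the authors' value table the shift of chromosome 8 was 0.41. The share of cells therefore cannot be read from the shift. RNA alone cannot tell an extra copy from a regional response to the treatment or from a loss in the LIF cells. These cannot be told apart here, since no DNA was measured and the passages of the LIF cells are not clear from the labels.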
